A study of Mus musculus with 24 samples.

How the data were processed

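RNA from the olfactory epithelium of male C57BL/6J mice aged 8 weeks was sequenced after exposure to an odorant or to no odor. Per the labels, each mouse had 4 h of habituation and then 90 min of exposure to 10 µL of odorant on filter paper, and the 1:1 mixtures had the same volume. Tissue was taken after perfusion, RNA came from a detergent supernatant cleared of nuclei, and stranded poly(A) libraries were made. The 24 libraries form 2 batches of 12, named AD and OC after their odorants, each with its own no-odor control and 3 odorant groups, with 3 biological replicates per group.

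The deposited tables hold expected counts per Ensembl gene, one table per batch, not scaled between libraries. The labels name STAR 2.7.10b, Salmon 1.10.1 and R 4.4.2 with the mouse build GRCm39, but not the role of each or the annotation release. Each table has 57010 genes; 12.8% of the AD values and 12.6% of the OC values were not whole and were rounded, by at most 0.5 counts. Totals ran from 19003768 to 24802512 counts per library. Symbols, transcript lengths and GC content came from GENCODE M21, an annotation of the earlier build GRCm38, matched by Ensembl ID, so no coordinates are given. It named 52029 of the 57010 IDs, and IDs without a name held 0.313% of the AD counts and 0.321% of the OC counts. Predicted genes and IDs without a symbol are counted but not named.

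Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM scaling, with 1 fit per batch over its 12 libraries and 4 groups and no block. All tests were two-sided, a gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene is from this fit unless another is named. The filter left 19525 genes in the AD batch and 19175 in the OC batch, of which 928 and 924 were olfactory receptors. A standard error is the log2 fold change divided by the square root of F. The decanal and octanal responses were compared in 1 fit of all 24 libraries, as a difference of differences, over 20018 genes. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 36 lists of a comparison. Camera with a correlation estimated from the data, and fry, were run beside it. Shares of counts were compared by a two-sided exact permutation test, whose smallest p for 3 against 3 libraries is 0.1.

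The comparisons, lists, tests and the rule for naming genes were fixed before the data were examined. The rule took, for each odorant against its control, the 8 called genes with the largest rise and the 8 with the largest fall among those without overlap between the groups and with a mean count of at least 20, up to 3 members of each list past its test, the 3 receptors with the smallest p, 8 genes always given (Fos, Egr1, Nr4a1, Npas4, S100a5, Kirrel2, Omp and Gap43), and 5 genes by p elsewhere or where few passed. From these the text names mainly genes whose call held without any 1 library. Genes named outside the rule are members of the fixed lists, given as examples after their values were seen. Exceptions are Scd1, Scd2 and Col4a1, taken from an average over both batches that was chosen after the data were seen. Receptor classes were read from family numbers in RefSeq synonyms, a choice made after the names were seen, and the list of published acetophenone receptors was written from memory.

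Alternatives planned beforehand were DESeq2 size factors, no low-count filter, a filter of 1 CPM (counts scaled to the library size) in 3 libraries, a block for the replicate number, a robust fit, the Wald test of DESeq2 1.42.0, a fit of the 6 libraries compared, leaving out each library in turn, and adjustment over the receptor list alone. Added after the data were seen were loess offsets per library for transcript length and GC content, the same with the replicate block, and the mean level of the marrow and bone lists as a covariate. The pipeline was tested on simulated counts made from the deposited libraries. The 2-fold and 4-fold changes were given only to genes with a mean over 1 CPM, so the percentages do not cover lower genes. For acetophenone against its control the pipeline found 79% of genes given a 2-fold change and 99% of those given a 4-fold change, with 12 false calls among 206. For octanal against its control these were 80%, 95% and 8 of 201. In a simulated table with a length trend alone, 8738 calls fell to 6 under the length and GC offsets.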

Results

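Messenger RNA of the mouse olfactory epithelium was counted in 24 libraries from 8 groups of 3 mice. In the AD batch, mice had no odor, acetophenone (an aromatic ketone), decanal (a straight-chain aldehyde) or a 1:1 mixture of both. In the OC batch they had no odor, octanal (a shorter straight-chain aldehyde), cis-3-hexenol (an unsaturated alcohol) or a 1:1 mixture of both. Totals ran from 20604861 to 24802512 counts per library in the AD batch and from 19003768 to 24531349 in the OC batch. Olfactory receptors took 0.515% ± 0.0169 of counts (SD, n = 3) in the AD controls and 0.371% ± 0.051 in the OC controls, and transcripts encoded by mitochondrial DNA took 0.260% ± 0.0237 and 0.794% ± 0.173. The AD and OC controls differ in batch as well as in mice, so levels are compared within a batch. The first principal component held 26.1% of the variance of the AD libraries and 24.97% of that of the OC libraries.

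**Figure D1:**
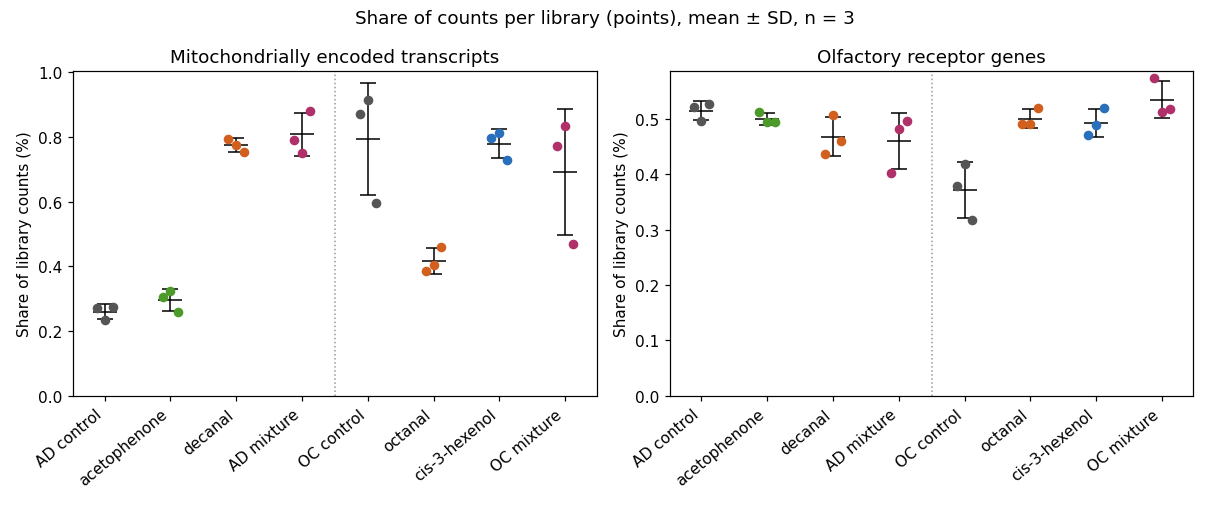
Percent of each library's counts in olfactory receptors and in mitochondrially encoded transcripts, by group, with each library as a point and the mean and SD of 3 libraries per group. Mitochondrial shares averaged 0.260% in AD controls and 0.774% with decanal, and receptor shares averaged 0.371% in OC controls and 0.535% with the OC mixture.

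Acetophenone was compared with no odor to ask which genes of the epithelium answer to this ketone. Il33 (ENSMUSG00000024810), which encodes an alarmin cytokine stored in nuclei of epithelial cells, rose from 496 ± 12.7 to 676 ± 32.0 CPM (SD, n = 3), a log2 fold change of 0.45 (SE 0.05, adjusted p = 0.00653). It was the 1 gene called of 19525, with 1287 genes at an unadjusted p under 0.05, 25 called by DESeq2 and 300 by edgeR with no low-count filter. Next by p stood the collagenase gene Mmp13, at a log2 fold change of -0.64 (adjusted p = 0.129), the gland lipase gene Pnliprp1, at 4.35 (adjusted p = 0.366), and Olfr819, at -2.36 (adjusted p = 0.412). The 6 genes known to be higher in more active olfactory sensory neurons had a median log2 fold change of 0.26. Among them Lrrc3b stood at 0.41, Kirrel2 at 0.31, Pcp4l1 at 0.23 and S100a5 at 0.02. None of the 6 was called over all genes, 2 were higher when adjusted over the list alone, and the list had adjusted p = 0.00167, or adjusted p = 0.355 with an estimated correlation. Early response genes were not called either, with Nr4a1 at 0.62, Fosb at 1.43, Npas4 at 0.74, Egr1 at 0.29 and Fos at -0.37.

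Among receptors, 0 of 928 passed with acetophenone in edgeR, adjusted over all genes or adjusted over the list alone, with 128 at an unadjusted p under 0.05 and 0 called by DESeq2. With no low-count filter edgeR called 28 receptors. The 8 receptors published as responsive to acetophenone had a median log2 fold change of -0.42, with Olfr744 at -1.55, Olfr145 at -0.66 and Olfr160 at -0.50, and 2 of them were lower when adjusted over the list alone. The 104 class I receptors, the class shared with fish, had a median of -0.49, and the 814 class II receptors one of -0.07. The 8 trace amine-associated receptors had a median of -0.38. The neutrophil and marrow list had a median of -1.32 over 8 genes and the erythroid list -0.52, while the vomeronasal organ list, at -1.84, did not pass (adjusted p = 0.063). By the preset correlation 18 of 36 lists passed, those of published acetophenone receptors (adjusted p = 0.000604), class I receptors (1.72e-20), marrow (1.72e-20), heat shock proteins (5.74e-06, median 0.18) and mitochondrially encoded transcripts (2.65e-06, median 0.24) among them, and 0 passed with an estimated correlation. In that order their values were adjusted p = 0.17, 0.355, 0.0674, 0.355 and 0.355 with an estimated correlation. Others past the preset test were lists of ensheathing and Schwann cells (median -0.35), globose basal cells (0.14), olfactory bulb (-1.14), skeletal muscle (-0.71), bone (-0.13), ciliated cells (0.07), ribosomal proteins (0.06) and enzymes of aldehyde, alcohol and ketone metabolism (0.09), with adjusted p from 0.17 to 0.481 with an estimated correlation. Of the 6 fits that leave out a library, the ciliated list passed in 2, the muscle and aldehyde enzyme lists in 3, the bone and class II receptor lists in 4, and the heat shock and active neuron lists in 5, all but that without acetophenone 2. The ciliated and muscle lists also lost their calls after correction for length and GC. The call of Il33 ended without AD control 1 or AD control 3, and the count of genes rose to 39 without acetophenone 1.

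Decanal was compared with no odor in the same batch. Transcripts encoded in mitochondrial DNA rose, 14 of the 15 tested, by a median log2 fold change of 1.62, with mt-Nd1, a subunit of respiratory complex I, 3.08-fold higher (log2 SE 0.08, adjusted p = 1.71e-08). Their share of counts was 0.260% in the AD controls and 0.774% with decanal. It was 0.794% in the OC controls, so a share as high also occurred without odor, in the other batch. Nuclear genes for cytosolic ribosomal proteins rose nearly as a block, 76 of 77, by a median of 0.47, with Rps19 at 0.55 and Rpl32 at 0.50. Markers of blood and marrow rose too: Hbb-bs, an adult beta-globin, by 2.05 (SE 0.25), and the neutrophil granule genes Camp by 2.96 (SE 0.39), Ngp by 2.47 and Elane by 2.59. Bone genes moved the same way, with the osteoblast gene Bglap at 0.88 (SE 0.10) and Ibsp at 0.59, as did the complement genes C1qa at 0.61, C1qb at 0.67 and C1qc at 0.62. Correction for length and GC lowered several of these while they stayed called: Bglap to 0.42, Rpl32 to 0.21, C1qa to 0.33, C1qb to 0.41 and C1qc to 0.39.

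Of 19525 genes, 2223 rose and 2437 fell with decanal, and 40.7% of genes had no overlap between the 3 libraries of each group, against 10% by chance. Falls were small: 40 of them and 270 of the rises exceeded 2-fold. Grm2, a metabotropic glutamate receptor gene, fell by 5.48 on the log2 scale (SE 0.98, adjusted p = 0.000916). Shorter transcripts rose and longer ones fell, with a median length of 1779 bases among the genes that rose and 4160 among those that fell, and a Spearman correlation across genes of -0.35 between fold change and length. S100a5, a calcium-binding protein gene of active sensory neurons, was called at 0.39 but stood at -0.05 after correction for length and GC, and Rplp1 was no longer called. With the level of marrow and bone genes as a covariate 25 genes passed with decanal and 6 with the AD mixture, but 95.7% of the variance of that covariate lay between the AD groups.

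Signs of odorant-driven transcription were few with decanal. Of 30 immediate early genes 1 rose and 3 fell (list adjusted p = 0.91); Egr1 was at -0.57 but was called in 1 of 6 fits that leave out a library, Fos stood at -0.24 and Nr4a1 at 0.13, neither called. Omp, the marker of mature sensory neurons, stood at 0.13 (adjusted p = 0.104), and Gap43, that of immature ones, at 0.13. The transduction genes Adcy3 (log2 fold change -0.40) and Gnal (-0.38) were among 9 of 19 transduction and mature neuron genes that fell, with a list adjusted p = 0.0512. Receptors were called 9 higher and 33 lower over all genes and 0 adjusted over the list alone, with 97 at an unadjusted p under 0.05 and 43 called by DESeq2 over all genes. Olfr1258 and Olfr1242 both fell by 0.75, and Olfr1463 fell by 0.53. The receptor count was 20 without AD control 3.

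For decanal 6 lists passed, all upward. With an estimated correlation the mitochondrially encoded list kept its call (adjusted p = 0.00887), while the ribosomal list had adjusted p = 0.0539, erythroid and marrow lists 0.16, bone 0.433 and other leukocytes 0.505. Il33, called with acetophenone, stood lower with decanal, at 417 ± 2.68 CPM.

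The AD mixture was compared with no odor and with its components to ask whether a mixture acts as the sum of its parts. It moved the same groups as decanal: mt-Nd1 rose by 1.71 (SE 0.08), Camp by 3.50, Ngp by 3.01, S100a9 by 2.31 and Bglap by 1.24, and 76 of 77 ribosomal protein genes rose by a median of 0.57, with Rpl35 at 0.79. After correction for length and GC, Bglap stood at 0.75 and Rpl35 at 0.51, both still called. Some genes of active neurons were called as well. The early response gene Nr4a1 rose by 0.92 (SE 0.17, adjusted p = 0.00142). The leucine-rich repeat gene Lrrc3b rose by 0.64 (SE 0.10, adjusted p = 0.00032) and the protocadherin gene Pcdh10 by 0.92 (SE 0.20). The mixture and decanal had no gene called between them in this fit, so a difference from decanal in these genes is not shown. Of 19 transduction and mature neuron genes 11 fell, with the phosphodiesterase gene Pde1c at -0.63 and the adenylyl cyclase gene Adcy3 at -0.51, and 1, Gng13, rose by 0.61. The list had adjusted p = 0.00651, or 0.701 with an estimated correlation, and its call ended without AD mixture 1. Coch, at 0.56, and Hepacam2, at 0.60, markers of microvillar cells, rose, and Nefh, a neurofilament gene, fell by 1.08.

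In all 2078 genes rose and 2269 fell with the AD mixture, and 36.6% of genes had no overlap between groups (10% by chance). Receptors called were 4 higher and 42 lower over all genes and 7 lower adjusted over the list alone, with Olfr1258 at -0.81, Olfr1395 at -0.74 and Olfr1463 at -0.68; the count was 19 without AD control 3. Of 9 lists past the preset test, mitochondrially encoded transcripts (adjusted p = 0.00751) and ribosomal proteins (adjusted p = 0.0208) passed with an estimated correlation. The others had adjusted p = 0.0779 (marrow), 0.119 (erythroid and microvillar cells), 0.211 (bone), 0.39 (other leukocytes) and 0.555 (genes of active neurons) with an estimated correlation. S100a5 was called at 0.41 but stood at -0.08 after correction for length and GC, where Gng13 and the ionocyte gene Ascl3 (0.43) lost their calls as well.

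Against decanal, the AD mixture gave 0 called genes in edgeR, with 1090 at an unadjusted p under 0.05 and 2 called by DESeq2, and 132 in edgeR with no low-count filter. Decanal and the mixture shared 3416 genes changed in the same direction and 0 in opposite directions, against 520 shared for independent calls, with a Pearson r across genes of 0.77 where simulated groups that share the controls gave 0.48 (genes are not independent replicates). The 520 takes no account of the shared controls. The simulation drew each gene independently, so neither value allows for a shift of many genes together in those controls. Against acetophenone, the mixture had 2259 genes higher and 2688 lower, led by mt-Nd2 at 1.58 (SE 0.08) and mt-Nd1 at 1.48. Decanal against acetophenone gave 2458 higher and 2821 lower, led by mt-Nd1 at 1.39, with mt-Rnr2 at 1.73 (SE 0.11). Receptors called over all genes were 93 higher and 56 lower for decanal against acetophenone, and 33 higher and 74 lower for the mixture against acetophenone. Adjusted over the list alone, they were 57 higher and 39 lower for decanal, and 11 higher and 34 lower for the mixture. Set against the mean log2 level of its single odorants, the mixture differed in 588 genes upward and 683 downward. That mean matches the amount of each component only if log2 levels follow the amount linearly. The neutrophil and macrophage gene Chil3 at 2.16 (SE 0.18), S100a9 at 2.02 and mt-Nd1 at 0.79 led these genes, and the count was 709 without AD mixture 1. Since the mixture was so like decanal, this contrast also carries the difference of decanal from acetophenone. It does not by itself show a departure from additivity.

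**Figure D2:**
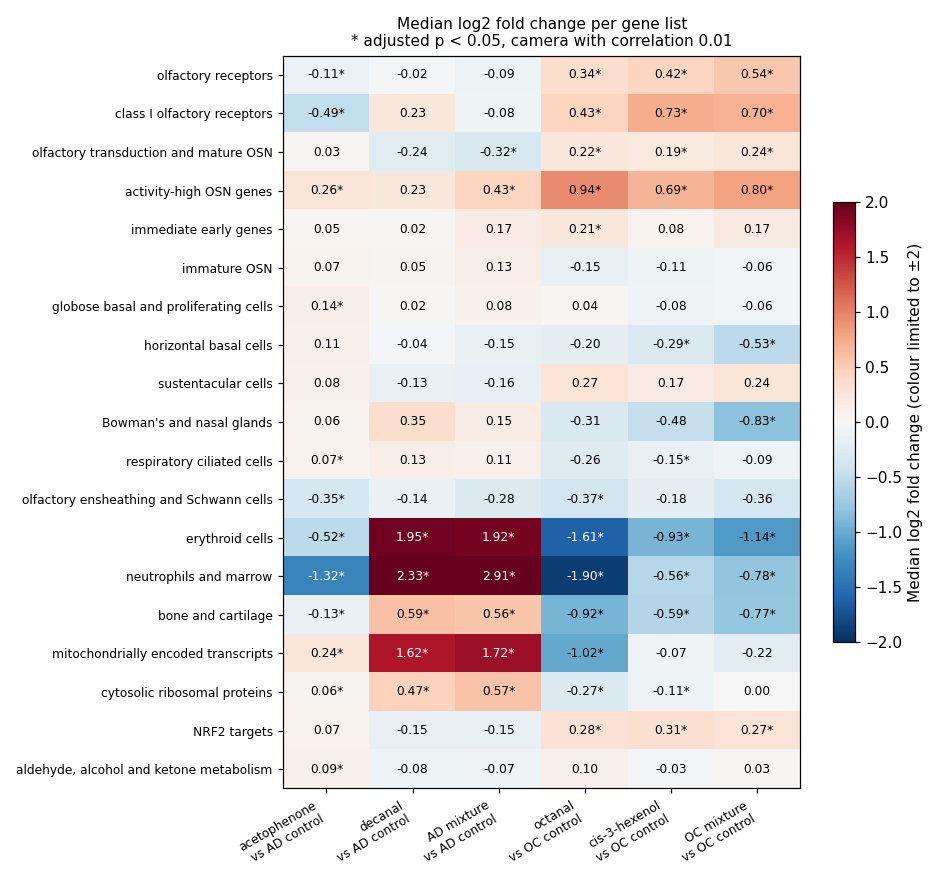
Median log2 fold change of the members of fixed gene lists for each odorant group against the no-odor control of its batch. Mitochondrially encoded transcripts stand at 1.62 with decanal and at -1.02 with octanal, and genes of active neurons at 0.43 with the AD mixture and 0.80 with the OC mixture.

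Octanal was compared with the no-odor control of the OC batch. Some genes that active sensory neurons raise went up: the early response genes Fosb by 3.17 (SE 0.55), Nr4a1 by 1.99 (SE 0.32, adjusted p = 0.000439), Nr4a2 by 1.52 and the feedback phosphatase gene Dusp6 by 0.44, and the slower activity genes Lrrc3b by 1.27 (SE 0.14), Sema7a by 1.13 and Pcp4l1 by 0.77. S100a5 at 0.24, Kirrel2 at 0.58, Fos at 0.94 and Npas4 at -0.75 were not called, though S100a5 was after correction for length and GC, at 0.54 (adjusted p = 0.00186). The lists of active neuron genes and immediate early genes had adjusted p = 0.385 and 0.615 with an estimated correlation. Olfr1257 rose by 1.11, Olfr1463 by 0.96 and Olfr1110 by 0.81 among 157 receptors that rose, with 4 that fell; the count of both was 105 without octanal 3 and 92 after correction for length and GC. Targets of NRF2, a transcription factor of the response to oxidants and electrophiles, rose in 6 of 10 cases. Among them were G6pdx at 0.78, Txnrd1 at 0.49 and Srxn1 at 0.46, while Slc7a11 fell by 1.18. The cytochrome gene Cyp2f2 rose by 0.72 and Fmo2 by 0.50.

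Transduction genes rose with octanal in 9 of 19 cases, with the chloride channel gene Ano2 at 0.73 and Pde1c at 0.68, but Omp fell by 0.45 (SE 0.05). Blood, marrow and bone genes fell: Hbb-bs by 1.61 (SE 0.28), S100a9 by 1.52, Ngp by 2.11, Col1a1 by 1.27 (SE 0.16) and Bglap by 1.04, and so did mt-Rnr2, by 1.46 (SE 0.19), and Fabp7, a marker of ensheathing glia, by 0.68. In all 2770 genes rose and 2870 fell, 89 and 376 of them over 2-fold, and 40.4% of genes had no overlap between groups (10% by chance). The count was 4945 without OC control 3, where the gland genes Mup4 at 7121 and Dnase1 at 59.1 CPM stood far above the other controls, at 215 or less and 3.43 or less. Adjusted over the list alone, 114 receptors were higher and 1 lower.

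Of 36 lists 15 passed with octanal and 0 with an estimated correlation. The lists of receptors, NRF2 targets, marrow, bone, erythroid cells, other leukocytes, ensheathing cells and mitochondrially encoded transcripts each had adjusted p = 0.385 with an estimated correlation, transduction, xenobiotic enzymes and ribosomal proteins 0.667, and class I receptors 0.745. Calls ended without octanal 3 for the ensheathing list, without OC control 1 or octanal 3 for class I receptors, which also lost theirs after correction for length and GC, and in 4 of 6 fits for xenobiotic enzymes. The immediate early list, 8 higher and 3 lower of 30, lost its call without OC control 2 or OC control 3. Egr1, at 0.93, was called in 3 of 6 fits that leave out a library. Bglap stood at -0.65 after correction for length and GC, still called.

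Cis-3-hexenol was compared with the same control. The lists of active neuron genes, NRF2 targets and receptors passed upward by the preset correlation but had adjusted p = 0.284, 0.277 and 0.277 with an estimated one. Lrrc3b rose by 0.97 (SE 0.14, adjusted p = 0.00312) and Sema7a by 0.86 (SE 0.16), while S100a5 at 0.27, Kirrel2 at 0.0742, Nr4a1 at 0.73 and Fosb at 1.07 were not called. The early response gene Npas4 was called lower, at -1.56, but in 1 of 6 fits that leave out a library. G6pdx rose by 0.54 (SE 0.08), Osgin1 by 0.45 and Srxn1 by 0.40, all NRF2 targets. Olfr1463 rose by 0.70 (SE 0.10), and Olfr1110 and Olfr309 rose by 0.65 each, or 0.43, 0.43 and 0.41 after correction for length and GC, still called. Omp fell by 0.31, and the bone collagen genes Col1a1 by 0.83 and Col1a2 by 0.73. Mitochondrially encoded transcripts had a median of -0.07 and did not pass as a list (adjusted p = 0.487), but passed downward after correction for length and GC (adjusted p = 0.00369).

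Cis-3-hexenol had 1066 genes higher and 1275 lower, with 30.6% of genes without overlap (10% by chance). Receptors were called 87 higher and 0 lower over all genes and 56 higher adjusted over the list alone, and the median receptor stood at 0.42. After correction for length and GC, 28 receptors and 1303 genes were called. Class I receptors, of which 10 of 108 rose, had a median of 0.73, with Olfr609 at 1.31 and Olfr16 at 0.92, both no longer called without cis-3-hexenol 3. The gene count rests on single libraries: 533 without cis-3-hexenol 3, 1498 without OC control 3 and 3150 without OC control 2, and the receptor count was 18, 39 and 171 in these fits. By the preset correlation 14 lists passed and with an estimated one 0, where bone had adjusted p = 0.32 and class I receptors 0.585.

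The OC mixture was compared with no odor. Of 924 receptors 253 were called higher and 0 lower over all genes (84 after correction for length and GC), and 266 higher adjusted over the list alone, and the list had adjusted p = 0.214 with an estimated correlation. Receptors had a median log2 fold change of 0.54, with Olfr1110 at 1.05 (SE 0.10), Olfr309 at 1.01 and Olfr1463 at 0.96. After correction for length and GC, Olfr309 stood at 0.65 and Olfr1463 at 0.57, still called. Lrrc3b rose from 62.8 ± 11.1 to 184 ± 31.2 CPM (SD, n = 3), a log2 fold change of 1.55 (SE 0.14, adjusted p = 5.2e-05), Pcdh10 by 1.54, Sema7a by 1.06 and S100a5 by 0.45. Fosb rose by 2.79 and Nr4a1 by 1.62. In the fit of all 24 libraries, Npas4 stood at -1.06, Fos at 0.54, Egr1 at 0.39 and Kirrel2 at 0.21 with the OC mixture. Omp fell by 0.32 (SE 0.05). Ric8b, a chaperone of the olfactory G protein, rose by 0.59, and the NRF2 targets G6pdx by 0.60, Srxn1 by 0.44 and Txnrd1 by 0.40. Keratin genes of horizontal basal cells, the reserve stem cells of the epithelium, fell, Krt5 by 0.50 (SE 0.07), Krt17 by 0.55 and Krt14 by 0.36, as did Col1a1 by 1.27 and Ngp by 1.16.

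In all 2211 genes rose and 2436 fell with the OC mixture, with 34.6% of genes without overlap (10% by chance). The receptor count was 145 without OC mixture 1 and 170 without OC control 3, and the median receptor stood at 0.32 after correction for length and GC; the gene count was 3035 without OC mixture 1. Receptor share of counts was 1.44 times that of the controls, against 1.35 times with octanal and 1.33 times with cis-3-hexenol, each with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Of 14 lists past the preset test 0 passed with an estimated correlation: genes of active neurons and horizontal basal cells had adjusted p = 0.214, bone 0.233, NRF2 targets 0.415, transduction (11 higher and 2 lower of 19) 0.696 and glands 0.734 with an estimated correlation. Of the gland list Muc5b fell by 1.02, a call lost after correction for length and GC, and the list lost its call without OC control 3 or OC mixture 1.

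Between the OC odorant groups no gene was called in the edgeR fit of all 12 libraries with its filter. With no low-count filter edgeR called 475 genes for the OC mixture against octanal, 188 for it against cis-3-hexenol, 581 for cis-3-hexenol against octanal and 229 for the OC mixture against the mean of its single odorants, and a fit of 6 libraries called 803 for cis-3-hexenol against octanal. With the filter, the OC mixture against octanal gave 0 genes, with 2447 at an unadjusted p under 0.05 and 256 called by DESeq2 (23 in edgeR without OC mixture 3), and against cis-3-hexenol 0, with 1187 and 16. Cis-3-hexenol against octanal gave 0 genes, with 2496 and 243, and the mixture against the mean of its single odorants gave 0, with 1563 and 30. Genes changed in the same direction numbered 2111 for octanal and cis-3-hexenol, 3534 for octanal and the mixture and 2157 for cis-3-hexenol and the mixture, with 0 in opposite directions in each pair. Pearson correlations across genes were 0.70, 0.74 and 0.75, where simulated groups that share the controls gave 0.49, 0.50 and 0.49. The simulation drew each gene independently, so it holds no shift of many genes together in the shared controls. Such a shift would also raise these correlations, so the excess does not by itself show alike responses. Lists of immature neurons, sustentacular cells, vomeronasal organ and receptors, circadian clock, glucocorticoid response, unfolded protein response, interferon response, inflammatory cytokines and low-activity neurons passed in none of the 6 odorant comparisons, the lowest adjusted p being 0.0507 for interferon response with the AD mixture, where it passed after correction for length and GC (0.0358).

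**Figure D3:**
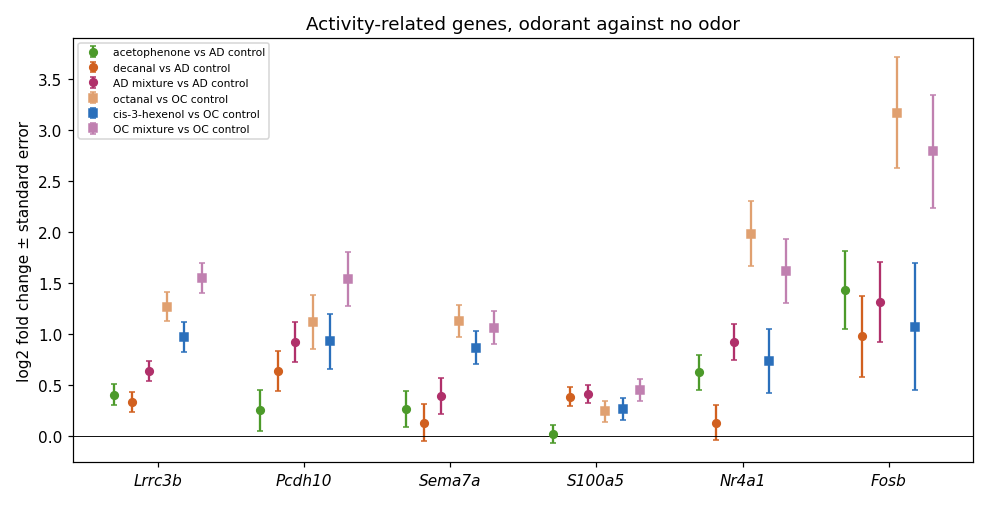
Log2 fold change with its standard error of Lrrc3b, Pcdh10, Sema7a, S100a5, Nr4a1 and Fosb, for each odorant group against the no-odor control of its batch. In CPM, which are not plotted, Lrrc3b averaged 184 over 3 libraries with the OC mixture against 62.8 in the OC controls. With the AD mixture it averaged 128 against 81.9 in the AD controls.

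Decanal and octanal are straight-chain aldehydes that differ in chain length by a pair of carbons, given in the same volume for the same time but in different batches. Their responses, each against its own control, differed in 7845 of 20018 genes, 4248 higher and 3597 lower with decanal. The mitochondrial gene mt-Nd6 rose by 1.81 with decanal and fell by 1.28 with octanal, a difference of 3.09 (95% interval 2.68 to 3.50). Some NRF2 targets differed the other way: G6pdx by -1.13 (-1.33 to -0.92), Txnrd1 by -0.86 (-1.04 to -0.68) and Gclc by -0.82 (-1.04 to -0.61), while Hmox1 differed by 0.40 (0.13 to 0.67). The list of NRF2 targets had adjusted p = 0.00833, or 0.423 with an estimated correlation. Of the aldehyde dehydrogenase genes, Aldh3a2, which oxidises fatty aldehydes, differed by -0.90 (-1.07 to -0.72), Aldh1a3 by -0.76 (-1.05 to -0.47), Aldh1a7 by -0.41, Aldh9a1 by -0.31 and Aldh2 by -0.30, but Aldh3a1 (adjusted p = 0.103), Aldh7a1 (0.0967), Aldh3b1 (0.618) and Aldh1a1 (0.258) did not pass. Early response genes that passed mostly differed downward: Nr4a1 by -1.83 (-2.62 to -1.04), Nr4a2 by -1.56 (-2.19 to -0.93) and Fosb by -2.18. Egr1 differed by -1.48, Arc by -0.96, Dusp6 by -0.52, Nfil3 by -0.52, Dusp1 by -0.47 and Homer1 by -0.46. The other way went Gadd45g by 0.72, Fosl2 by 0.56 and Ier2 by 0.43. The list of immediate early genes did not pass (adjusted p = 0.228). Omp differed by 0.60 (0.45 to 0.76).

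Several genes did not separate the aldehydes: Aldh1a1 differed by -0.20 (-0.47 to 0.07), Adh7 by -0.05 (-0.42 to 0.31) and Jun by -0.09 (-0.25 to 0.07), intervals that allow differences of either sign. S100a5 differed by 0.17 (-0.13 to 0.46), but after correction for length and GC, which was not run on the difference, it stood at -0.05 with decanal and 0.54 with octanal. In the same fit decanal changed 4101 genes and octanal 6447. Of 2542 genes changed by both, 2508 moved in opposite directions and 34 in the same, against 661 and 660 for independent calls, and Pearson r across genes was -0.35 and Spearman rho -0.47. Mitochondrially encoded transcripts differed by a median of 2.65 (adjusted p = 0.0677 with an estimated correlation), ribosomal protein genes by 0.74 (0.231), marrow genes by 4.31 (0.158) and receptors by -0.31 (0.704), each past the preset test. Aldehyde, alcohol and ketone enzymes as a list did not pass (adjusted p = 0.221). Without OC control 3 the count was 7536. Compound and batch change together here, so a difference between batches cannot be told apart from one between the aldehydes.

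**Figure D4:**
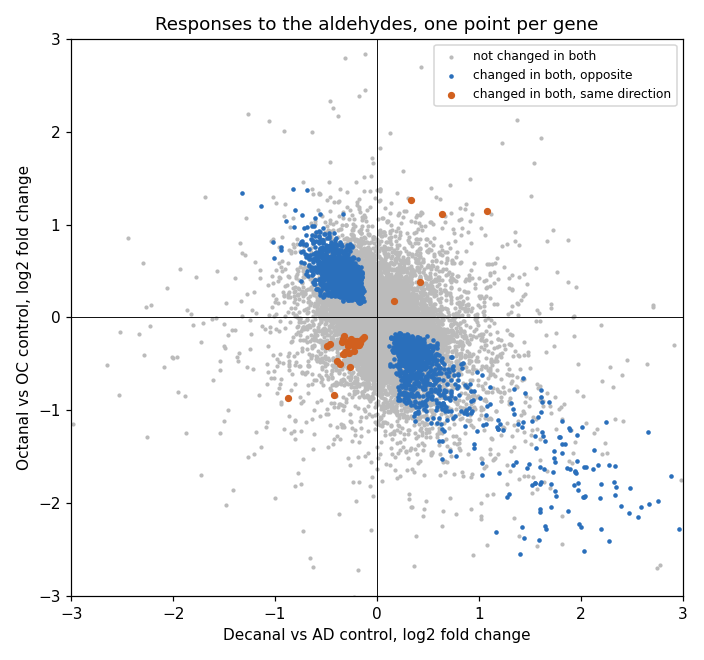
Log2 fold change of each gene with octanal against that with decanal, each against the control of its batch, for 19015 genes, with genes called in both marked. Of these, 2537 moved in opposite directions and 37 in the same, with 45 genes outside the plotted range.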

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

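The length and GC correction, the tests on corrected values and the marrow and bone covariate were chosen after the data were seen, and the numbers of splits drawn beyond the first draw were set then too. The other tests here were planned or had their bounds written before their results. The responses to decanal and octanal were singled out because a test of the difference between them passed for 7845 genes, and because 2508 genes changed in both moved in opposite directions. Of 75 splits drawn from the AD and OC libraries concerned, 1 gave as many genes as the real one, the real split itself, with 4308 the highest of the others. These splits exchange the libraries of each aldehyde with those of its control. They cannot tell a difference between the aldehydes from a response to either. The same count had flagged the result, so no conclusion on chance is drawn. Which part of the count belongs to the compounds and which to the batches was not tested, since each aldehyde was used in 1 batch.

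In the AD batch, decanal and the mixture stood apart from the control and acetophenone, with mitochondrial, ribosomal, marrow and bone genes higher and long transcripts lower. Transcript length and GC bias as the whole cause is argued against by the 3270 genes still called for decanal after the correction, of 4660 before it. Marrow and bone tissue in the dissection may be part of it: with those lists as a covariate 25 genes were called, but the median size of change went from 0.34 to 0.29 while the median standard error went from 0.0709 to 0.172, so the calls ended mainly by lost precision, and tissue and group cannot be told apart where 95.7% of the covariate lies between groups. A response in proportion to the amount of decanal would give a slope near 0.5 of mixture minus acetophenone on decanal minus control; it was 0.924, and 0.681 without AD control 3 to 0.987 across fits that leave out a library, which leaves it open. A response to decanal and an unrecorded difference in how these mice were handled both stay open and untested, since the labels give no dates within a batch.

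In the OC batch, the control stood apart from octanal, cis-3-hexenol and their mixture, which had 0 genes called between them in the edgeR fit of all 12 libraries (for cis-3-hexenol against octanal 2496 at an unadjusted p under 0.05, 243 by DESeq2, and in edgeR 803 with 6 libraries and 581 with no low-count filter). Length and GC bias as the whole cause is argued against by 4578 genes called for octanal after the correction, of 5640 before it. A response common to any odorant might explain the likeness of the OC groups. Their mean response had a correlation across genes of -0.319 with the decanal response, which shares no library with it (-0.345 to -0.214 across fits that leave out a library). With the acetophenone response it was 0.0198. This goes against a common response as the whole source only if the decanal contrast holds no difference in handling or tissue, which stays open. In an average over both batches, chosen after the data were seen, 2645 of 20018 genes were called. Of these, 816 had the same sign in all 6 comparisons, which share controls within a batch. The genes were picked by their average over the same comparisons, which favors equal signs. No number expected without a common response was computed, so the 816 decide nothing on it. A response shared by the OC odorants and a difference in the handling of the control mice stay open and untested.

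Of 924 receptors 157 were called higher with octanal, 87 with cis-3-hexenol and 253 with the OC mixture, but their list had adjusted p = 0.385, 0.277 and 0.214 with an estimated correlation, and the octanal median turned to -0.13 with the marrow and bone covariate. A larger share of mature sensory neurons in the tissue could raise them: in the OC mixture the median receptor rose by 0.54 and the median of 19 transduction and mature neuron genes by 0.24, a gap of 0.30, but after the length and GC correction the medians were 0.32 and 0.27, a gap of 0.0550. Omp, the marker of mature neurons, fell by 0.32 with the OC mixture (0.23 after the correction), which goes against a larger share, but 1 gene excludes nothing and it stays open. Length and GC bias could account for part: the median receptor fell from 0.54 to 0.32 after the correction, between the bounds set for a cause and for none, so the part it accounts for stays open. Receptors called in either direction went from 161 to 92 with octanal, 87 to 28 with cis-3-hexenol and 253 to 84 with the OC mixture. A receptor response to these odorants also stays open, as untested.

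Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. The real split gave 4660 genes for decanal, 4347 for the AD mixture, 4947 for the AD mixture against acetophenone, 5279 for decanal against acetophenone and 5640 for octanal, each with 0 as the highest of the other splits, and 2341 for cis-3-hexenol and 4647 for the OC mixture, each with 1; in these, 1 split reached the real count. For acetophenone 2 splits gave as many as the 1 gene called, the highest other giving 2. The real count was 0, with 10 splits as large, for the AD mixture against decanal (highest other 1; 1090 at an unadjusted p under 0.05, DESeq2 2), the OC mixture against octanal (0; 2447, 256), the OC mixture against cis-3-hexenol (1; 1187, 16) and cis-3-hexenol against octanal (0; 2496, 243). For the AD mixture against the mean of its single odorants, 4 of 100 splits drawn gave as many genes as the real 1271, but the draw was enlarged after a smaller one, whose share lay above 0.05, had been seen, so whether chance accounts for the count stays open. The highest other gave 6185 with the acetophenone libraries in the place of the mixture, which points to a structure of the samples, and the other splits that reached the count exchanged decanal and mixture libraries. The OC mixture against the mean of its single odorants gave 0 genes (1563 at an unadjusted p under 0.05, DESeq2 30), a count that all 100 splits reach by construction, the highest other with 58, so the splits say nothing about chance there.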

How the results depend on the processing

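The length and GC correction, alone or with the replicate block, and the marrow and bone covariate were chosen after the data were seen; the other settings were planned. Of 343 values of named genes, 342 kept their direction and side of the threshold with DESeq2 size factors, 298 with no low-count filter (44 gained a call), 320 with the replicate block, 299 with the length and GC correction (40 lost a call) and 101 with the covariate (223 lost it). Replicate numbers did not pair the libraries, the mean correlation of equal numbers being 0.017 in the AD batch and -0.051 in the OC batch. Counts and shares that moved past the bounds set for them, and directions that turned, follow by setting; the cause was not tested unless stated.

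The Wald test of DESeq2 called 25 genes for acetophenone, 2 for the AD mixture against decanal, 256 for the OC mixture against octanal, 16 for it against cis-3-hexenol, 243 for cis-3-hexenol against octanal and 30 for the OC mixture against the mean of its single odorants. With no low-count filter, which tests more genes, the counts were 300 for acetophenone, 132 for the AD mixture against decanal, 1943 for the AD mixture against its mean, 475, 188 and 581 for the OC mixture against octanal, that against cis-3-hexenol and cis-3-hexenol against octanal, and 229 for the OC mixture against its mean. Receptors then numbered 28 for acetophenone, 68 for decanal, 81 for the AD mixture and 210 for cis-3-hexenol. Fits of only the 6 libraries compared, which hold fewer samples, called 5 genes for acetophenone, 1047 genes and 46 receptors for cis-3-hexenol, 2816 genes and 153 receptors for the OC mixture, and 803 genes for cis-3-hexenol against octanal. The robust fit called 1 gene for the AD mixture against decanal, and the replicate block 6 for cis-3-hexenol against octanal. Adjusted over the list alone, receptors numbered 0 for decanal, 7 for the AD mixture and 56 for cis-3-hexenol.

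Lists past camera with an estimated correlation were 0 for acetophenone (18 by the preset one), 1 for decanal (6), 2 for the AD mixture (9), and 0 for octanal (15), cis-3-hexenol (14) and the OC mixture (14). By fry, which compares a list with no other genes, they were 0 for acetophenone, 10 for decanal, 14 for the AD mixture and 8 for cis-3-hexenol.

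The length and GC correction gave 18 lists for the AD mixture, 1 gene for the AD mixture against decanal, 844 for the AD mixture against its mean and 1303 for cis-3-hexenol, with 92 receptors for octanal, 28 for cis-3-hexenol and 84 for the OC mixture. With the replicate block added it gave 3076 genes for decanal, 1 for the AD mixture against decanal, 823 for the AD mixture against its mean, 953 for cis-3-hexenol, 2953 for the OC mixture and 11 for cis-3-hexenol against octanal, with 85 receptors for octanal, 20 for cis-3-hexenol and 65 for the OC mixture. Under both, S100a5 turned to -0.0474 with decanal (-0.0475 with the block) and -0.0797 with the AD mixture (-0.0791), and Dnah9 with cis-3-hexenol to 0.0909 (0.0850).

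With the marrow and bone covariate, genes called were 0 for acetophenone, 25 for decanal and 6 for the AD mixture. They were 0 for octanal, cis-3-hexenol and the OC mixture. Receptors called were 0 for decanal, the AD mixture, octanal, cis-3-hexenol and the OC mixture. In the AD batch 95.7% of the variance of the covariate lay between the groups, and the median standard error for decanal went from 0.0709 to 0.172. Neither was measured in the OC batch, so why calls ended there was not tested. The marrow and bone marker genes are themselves in the covariate. With decanal Elane turned to -0.46, Retnlg to -0.46, Acta1 to 1.40 and S100a9 to -0.11. With the AD mixture Elane turned to -0.61, Retnlg to -0.71, Gap43 to -0.17 and Igkv6-23 to -1.75. With octanal the median receptor turned to -0.13, Camp to 0.54, Olfr610 to -0.16, Gap43 to 0.26, Rpl35a to 0.0819, Olfr666 to -0.26, Olfr665 to -0.97, Bglap to 0.16 and Olfr75-ps1 to -0.70. With the OC mixture Ngp turned to 0.28, Camp to 0.59 and S100a9 to 0.24.

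Leaving out each library in turn, genes ranged from 0 to 39 for acetophenone, 709 to 1340 for the AD mixture against its mean, 533 to 3150 for cis-3-hexenol and 3035 to 4960 for the OC mixture. They ranged from 0 to 23 for the OC mixture against octanal (23 without OC mixture 3), and from 0 to 1 for the AD mixture against decanal, the OC mixture against cis-3-hexenol, cis-3-hexenol against octanal and the OC mixture against its mean. Receptors ranged from 0 to 3 for acetophenone, 20 to 42 for decanal, 19 to 60 for the AD mixture, 105 to 201 for octanal, 18 to 171 for cis-3-hexenol and 145 to 300 for the OC mixture, and lists for the AD mixture from 9 to 16. The receptor share over that of the controls ranged from 1.26 to 1.44 for octanal, 1.24 to 1.42 for cis-3-hexenol and 1.34 to 1.54 for the OC mixture, lowest without OC control 3 and highest without OC control 2. The counts for decanal (3391 to 4145), the AD mixture (3087 to 4207), octanal (4054 to 5764) and the difference of the aldehydes (7101 to 7886) stayed within 1.5 times in these fits.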

Other observations

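The test of odorant against no odor across both batches, and the averaged fold changes here, were chosen after the data were seen. In both batches, genes known to be higher in more active olfactory sensory neurons (S100a5, Kirrel2, Lrrc3b, Pcp4l1, Pcdh10 and Sema7a, a list fixed beforehand) were higher as a group with odorant than without, and 5 of the 6 were called in the average over odorants; Kirrel2 was called in 0 of the 6 single comparisons. Their mean log2 level was higher by 0.32 in the AD batch and by 0.83 in the OC batch, and 16 of 18 odorant libraries lay above every control of their batch. By camera over both batches the list had adjusted p = 6.67e-11, but 0.0648 with an estimated correlation. Lrrc3b had a positive fold change in 6 of 6 comparisons, though it was not called with acetophenone. It was higher by 0.87 on average over the 6 odorant groups (SE 0.08, adjusted p = 2.67e-06 in edgeR). Pcdh10 was higher by 0.91 (SE 0.16), Sema7a by 0.65 and S100a5 by 0.31 (though not in the AD batch after the length and GC correction). The early response gene Nr4a1 was higher by 1.01 and Fosb by 1.81. Against this, the desaturase genes Scd1 and Scd2 were lower by a log2 of -0.44 and -0.32, and the basement membrane collagen gene Col4a1 by -0.59. Markers of olfactory ensheathing and Schwann cells, the glia around olfactory axons, were lower by a mean of -0.29 (exact permutation p = 0.00267, adjusted p = 0.048 over 36 lists, -0.32 to -0.24 without any 1 library). Of the 7 members 2 were called lower, and by camera over both batches the list had adjusted p = 0.00191, or 0.564 with an estimated correlation.

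A candidate explanation is that each odorant raised activity in enough sensory neurons to show in whole epithelium, in either batch and whichever way the batch's other genes moved. Naming any 3 of the 12 libraries of each batch as controls gives 48400 splits. Of these, 4 had a difference as large as the real 0.58, the highest other being 0.60 (exact permutation p = 8.26e-05, adjusted p = 0.00298 over 36 lists). Such splits exchange single libraries, so they cannot exclude a chance difference between whole groups. This test was also chosen after the data were seen. The difference was 0.59 after the length and GC correction and 0.51 to 0.70 without any 1 library. Within the AD batch the list passed camera for the AD mixture and acetophenone and not for decanal (adjusted p = 0.183), and no call held with an estimated correlation. The 30 immediate early genes differed by 0.16 (exact permutation p = 0.0377, adjusted p = 0.271), and all olfactory receptors had adjusted p = 0.396, so neither passed this permutation. By camera over both batches they had adjusted p = 0.0287 (7 genes called higher, 0 lower) and 2.92e-07 (55 higher, 1 lower), and each 0.564 with an estimated correlation. A difference in handling between control and odorant mice, present in both batches, would give the same result and was not tested.

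OC control 3 stood apart in gland genes: Mup4, a major urinary protein made by nasal and lacrimal glands, was at 7121 CPM against 107 and 215 in the other OC controls, Pnliprp1 at 42.3 against 0.734 and 0.723, and Dnase1 at 59.1 against 3.43 and 2.65. The calls of Mup4, Pnliprp1 and Dnase1 with the OC mixture ended without it. Npcd was at 4.58 CPM in the AD controls and 0.0839 with decanal, and at 0.0316 in the OC controls and 3.22 with octanal; reads shared with overlapping or related genes were not examined.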
